A study of Mus musculus with 12 samples.

How the data were processed

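Poly-A RNA was sequenced from primary glial cultures of the postnatal mouse cortex, labelled by the submitters as cultured astrocytes. Per the labels' protocols, cells came from CD1 mice of postnatal days 3 to 5, were grown with epidermal growth factor, and were used after 1 split. There were 3 groups of 4 libraries: vehicle control, 3 µM thapsigargin for 60 min, and calcium-free medium with EGTA for 60 min. Groups and replicate numbers were taken from the sample titles. The series text states that the 4 samples of a group are biological replicates. Per the labels' protocols, every sample had an RNA integrity number above 9.3, and stranded libraries of about 275 bp were made from 500 ng of RNA with 14 cycles of PCR. No molecular identifiers are described in the labels, so precision is that of read counts.

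Per the submitters' processing notes, bcl2fastq 2.20.0.422, cutadapt 1.17, STAR 2.7.2b and featureCounts 1.6.4 of the Subread package were used with the mouse genome GRCm39. The order and options of these steps, the strand setting and the read length are not given in the sources used here. The deposited table holds estimated counts per gene for 43322 genes and 12 libraries, with gene symbols, biotypes, summed exon lengths and GRCm39 coordinates. Between 14.2% and 15.9% of the values in a library were not whole, and they ended in fractions such as those of reads divided between features. These expected counts were rounded to whole numbers before any count model. No column held values of a sample outside these 12. Mitochondrially encoded genes carry their symbols without a prefix in the table (ND1, ATP6). H2bc23 and H2bc24 held nearly the same counts in every library, so the values of these 2 histone genes are not independent and are uncertain. Because the strand setting is unknown, overlapping and antisense genes are likewise uncertain.

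Library totals ran from 36.19 to 42.57 M counts. CPM values (counts scaled to a total of 1 M per library) were computed with normalised library sizes. Genes were tested with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with robust estimation, TMM normalisation, the default filter by group at a minimum count of 10, and 1 mean per group over all 12 libraries, so that the groups shared 1 estimate of the spread. This left 17077 genes. P-values were adjusted by Benjamini and Hochberg within each of the 3 contrasts, and genes were called at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the test statistic. On simulated data for thapsigargin versus control (17077 genes), the test recovered 22% of the 50 genes with the smallest simulated change, 68% at 1.5-fold, 84% at 2-fold and 98% at 4-fold, with 0 unchanged genes called. With the replicate number as a block, 74%, 86%, 96% and 98% were recovered and 14 unchanged genes were called, 7.33% of its calls. The counts were drawn from the fit with the block, its replicate terms and spread included, so the better recovery with the block was built in. Changed genes were taken only from those above a floor of mean counts. On 100 simulated lists of unchanged genes, camera gave 1 and fry 2 lists at p under 0.05. The simulated genes were drawn independently of each other. This check therefore cannot show how camera at the preset correlation behaves on lists whose genes vary together.

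Gene lists were fixed before the data were examined: 21 lists of pathways and 7 lists of cell type markers. Each was tested with camera on limma-voom values (limma 3.58.1, preset correlation 0.01), with camera at an estimated correlation and fry beside it, adjusted over the 28 lists of a contrast. Genes were named by a rule fixed at the same time. It took, for each contrast, the 6 largest increases and 6 largest decreases among called genes with an average log2 CPM of at least 2 and no overlap of libraries, leaving out unnamed, Gm and Rik symbols. It added the 3 members of each list with the smallest p for any difference among the groups, and a fixed set of calcium entry and stress genes, 114 genes in all. Every fixed list is reported, and 1 named gene is not reported here.

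The groups share the replicate numbers 1 to 4. Deviations from the group means correlated between libraries of the same number with r from 0.159 to 0.836 across genes, and every such pair was above 0.1, so the numbers were treated as pairing the libraries. The pairing came from replicate 4, with r from 0.814 to 0.836. Among numbers 1 to 3, r was 0.159 to 0.392 for the same number and 0.238 to 0.412 for different numbers, and with replicate 4 left out it was -0.144 to -0.00319 for the same number. The block by replicate number was therefore fitted as an alternative, and its value is given where it changes a call or moves a count of calls by over 1.5 times. Counts of 2 replicate libraries of a group differed by more than sampling noise in every pair (chi-square per degree of freedom from 1.663 to 19.05 among replicates 1 to 3 and from 38.11 to 46.13 with replicate 4), so none was merged with another as the same library. This does not show that replicates 1 to 3 had separate origins, for which the series text is the source.

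Alternatives fixed beforehand were DESeq2 1.42.0 with its size factors, RLE and upper quartile factors, no filter, a filter of 50 counts in 4 libraries, limma-voom, only the 8 libraries of a contrast, the replicate block, a 2-fold threshold, and leaving out each library and each replicate number. Alternatives added after seeing the data were a block for replicate 4 alone, tests without mitochondrially encoded genes, a correction of each library's trend with exon length, the block with each replicate number left out, the split of controls with the block, upper quartile factors for lists, and the length correction with the block for lists. Both treatments were compared with the same controls, so the correlation of their fold changes is given beside 20 simulations of unchanged groups and with the controls split. That simulation was rewritten after its first output was seen, because of an error in its construction, and the test of RNA recovery was changed to exact enumeration after its first result. Figures were drawn with matplotlib 3.10.9. No reads, protein levels or calcium measurements were analysed here.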

Results

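Gene expression was measured by poly-A RNA sequencing in 12 libraries of cultured mouse cortical glial cells, in 3 groups of 4. The series text describes the 4 samples of a group as biological replicates. Control cells received vehicle. Thapsigargin, an inhibitor of the SERCA pumps that fill the endoplasmic reticulum (ER) with calcium, was given at 3 µM for 60 min. The last group was kept for 60 min in calcium-free medium with EGTA, a calcium chelator, which takes away the calcium that store-operated channels admit from outside. The design asked which calcium signalling components change under SERCA blockade and without external calcium, and the series title also names cell stress. Library totals were 40.3 ± 2.13 M counts in controls, 42.1 ± 0.418 M with thapsigargin and 39.3 ± 2.51 M in calcium-free medium (SD, n = 4 each), and 17077 genes were tested.

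Replicate 4 of each group stood apart from replicates 1 to 3. Xist, the RNA that coats the inactive X chromosome, was at 605 to 734 CPM in the 3 libraries of replicate 4 and at 0.331 CPM or below in the other 9 libraries. Y-linked genes were at 190 to 230 CPM in replicates 1 to 3 and at 0.213 CPM or below in replicate 4, so replicate 4 differed from the others in sex. It also differed in cell markers in every group. The median of the proliferation markers was 191 to 208 CPM in replicate 4 and 124 to 143 CPM in the other libraries. That of the microglia markers was 7.64 to 9.77 CPM and 10.7 to 16.9 CPM. Whether these differences came from sex or from other traits of its culture was not tested. The values do not show that replicates 1 to 3 were separate cultures, so the number of independent cultures behind each n = 4 is uncertain. The first principal component held 44% of the variance, the second 21% and the third 12.9%. The share of counts from mitochondrially encoded genes was 2.73 ± 0.232% in controls, 2.36 ± 0.33% with thapsigargin and 1.98 ± 0.525% in calcium-free medium (SD, n = 4). The difference between calcium-free medium and control gave p = 0.0857 in a two-sided exact permutation test, adjusted to 0.171 over 9 such tests, where the smallest p possible is 0.0286. The share was lower than in the control of the same number in all 4 pairs, and an exact sign-flip permutation test of the pairs, added after the values were seen, gave p = 0.125, the smallest possible.

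**Figure D1:**
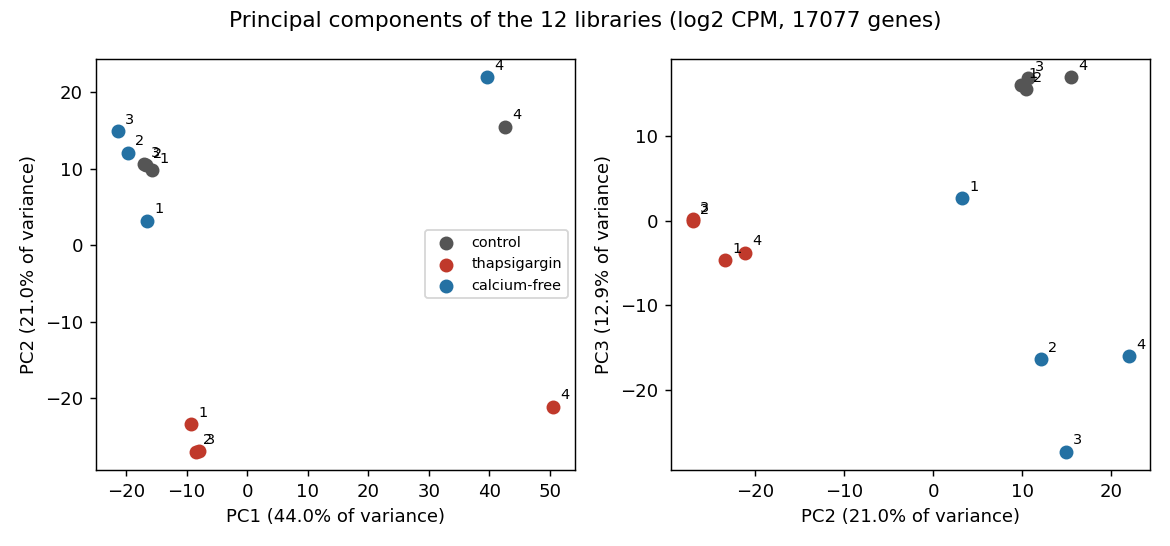
Principal components of log2 CPM, 1 point per library, coloured by group and marked by replicate. The first component holds 44% of the variance and the second 21%, and the 3 libraries of replicate 4 lie apart from the other 9.

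Thapsigargin raised activity-induced transcription factors within 60 min. Nr4a1, an orphan nuclear receptor induced by calcium and growth factor signals (gene 15370, GRCm39 chromosome 15, 101151783 to 101172676), rose from 16.4 ± 2.88 to 160.3 ± 41.9 CPM (SD, n = 4), a log2 fold change of 3.29 ± 0.20 (SE). Egr1, an early growth response factor (chromosome 18, 34994260 to 34998009), rose by 2.86 ± 0.16, and Fos, a subunit of AP-1 (chromosome 12, 85520664 to 85524048), by 2.54 ± 0.21. Rgs1, which shortens G protein signals, rose by 3.10 ± 0.16, and Gadd45g and Csrnp1, stress- and cytokine-induced genes, rose by 2.48 ± 0.09 and 2.39 ± 0.16. The 6 largest decreases were smaller and included Cemip2, a cell surface hyaluronidase (chromosome 19, 21755704 to 21835724), at -1.55 ± 0.15, the galactosyltransferase gene B4galt5 at -1.24 ± 0.11, the cyclin genes Ccne2 at -1.05 ± 0.12 and Ccnf at -0.99 ± 0.21, Megf6 at -1.01 ± 0.07, and Tram1l1 at -0.98 ± 0.09. Adjusted p for these 12 genes ran from 1.86e-08 to 0.00341. In all, 2800 genes were higher and 2531 lower than in control with edgeR, of which 170 and 20 changed at least 2-fold. With the replicate number as a block, 3920 were higher and 4817 lower. Higher genes were 52.5% of calls with TMM factors and 44.6% with upper quartile factors.

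Of 32 measured immediate early genes, 26 rose with thapsigargin and 0 fell (28 and 0 adjusted over the list alone), with a median log2 fold change of 1.48. Among them were Btg2, an antiproliferative gene, at 1.74 ± 0.07 and Klf2, a zinc finger factor, at 1.66 ± 0.09. The list was higher by camera (adjusted p = 2.17e-20), with adjusted p = 0.0698 with an estimated correlation. Npas4, a neuronal activity-regulated factor, was at 0.40 ± 0.18 (adjusted p = 0.106, 0.025 with the replicate block). Feedback regulators of MAP kinase signalling rose in 10 of 15 cases (10 adjusted over the list alone), among them the phosphatase gene Dusp6 at 1.44 ± 0.06 and the receptor signalling inhibitors Spry2 at 1.34 ± 0.08 and Spry4 at 1.18 ± 0.06. That list gave adjusted p = 1.25e-06, and adjusted p = 0.078 with an estimated correlation. Inflammatory and NF-kB targets rose in 14 of 23 cases (15 adjusted over the list alone), with Tnfaip3, a brake on NF-kB, at 1.31 ± 0.12, Socs3, a cytokine signalling inhibitor, up 2.37-fold, and the chemokine gene Cxcl1 at 3.09 ± 0.37 from 0.39 ± 0.236 CPM. Its camera test gave adjusted p = 3.13e-04, and adjusted p = 0.718 with an estimated correlation. Map3k14, the kinase of the noncanonical NF-kB pathway, rose 3.03-fold from 13.9 ± 0.838 to 42.2 ± 1.38 CPM. Circadian clock genes were higher in 8 of 17 cases (8 adjusted over the list alone), among them Nfil3, from 15.9 ± 1.87 to 35.7 ± 1.59 CPM, and Bhlhe40 at 0.77 ± 0.06, with adjusted p = 0.007, and adjusted p = 0.322 with an estimated correlation. The replicate block called 17 higher and 4 lower of the 23 inflammatory targets, and 10 higher and 1 lower of the 17 clock genes.

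ER stress genes moved in both directions. Atf4, the transcription factor of the integrated stress response (gene 11911, chromosome 15, 80139385 to 80141746), rose from 66.2 ± 2.38 to 279.6 ± 15.8 CPM, a log2 fold change of 2.08 ± 0.06. Atf3, a stress-induced factor, rose by 2.04 ± 0.12, Ddit3, which encodes the proapoptotic factor CHOP (chromosome 10, 127126662 to 127132160), by 1.32 ± 0.11, and Ppp1r15a, which directs dephosphorylation of eIF2alpha, by 1.19 ± 0.07. The ATF4 and integrated stress response list of 28 genes had 8 higher and 7 lower (8 and 10 adjusted over the list alone), with a median of -0.06, a mean of 0.23 and adjusted p = 0.655. Herpud1, an ER-associated degradation protein, rose by 0.83 ± 0.05 and Hspa5, which encodes the ER chaperone BiP, by 0.15 ± 0.03, while the chaperone genes Calr and Pdia6 fell by 0.22 and 0.21 on the log2 scale. ER chaperones as a list of 16 had 3 higher and 5 lower (3 and 5 adjusted over the list alone, adjusted p = 0.697). Xbp1, a transcription factor of the unfolded protein response, rose by 0.50 ± 0.07. The list of XBP1 targets and ER-associated degradation was lower, with 2 of 22 members higher and 12 lower (2 and 13 adjusted over the list alone) and a median of -0.17. Its lower members included Spcs3, a signal peptidase subunit, at -0.51 ± 0.04, Edem3 at -0.44 ± 0.04 and Dnajc10 at -0.39 ± 0.03. Its camera test gave adjusted p = 0.00358, and adjusted p = 0.322 with an estimated correlation. Of 12 unfolded protein response sensors, 1 was higher and 2 lower (1 and 1 adjusted over the list alone, adjusted p = 0.79), with Creb3l2 at 0.26 ± 0.04 and the protease gene Mbtps1 at -0.38 ± 0.05. The sensors had 2 higher and 3 lower with the replicate block.

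Components of store-operated calcium entry changed little at the RNA level. Of 18 measured, 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.8). The channel genes Trpc1 and Orai2 rose by 0.55 ± 0.07 and 0.31 ± 0.08, and Septin2, a regulator of Orai1, fell by 0.18 on the log2 scale. The ER calcium sensor gene Stim1 (chromosome 7, 101909279 to 102086525) was at 62.0 ± 5.26 CPM in control and 60.9 ± 4.45 CPM with thapsigargin (adjusted p = 0.856). The log2 fold changes were -0.12 ± 0.09 for Stim2, 0.13 ± 0.06 for Orai1, -0.03 ± 0.07 for Orai3 and -0.14 ± 0.06 for Saraf, an inhibitor of the entry. None of these 4 passed the test (adjusted p from 0.122 to 0.833). Atp2a2, the SERCA2 gene that encodes the target of the drug (chromosome 5, 122591576 to 122640288), was at -0.09 ± 0.03 (adjusted p = 0.0629). With the replicate block, Saraf (adjusted p = 0.00037), Atp2a2 (0.011), Stim2 (0.019) and Orai1 (0.028) were called. Among 25 calcium pumps, exchangers and release channels, 1 was higher and 5 lower (1 and 5 adjusted over the list alone, adjusted p = 0.248), with the mitochondrial uptake regulator Micu3 at 0.74 ± 0.10. Calmodulin, CaM kinases and calcium-binding proteins had 6 of 35 higher and 13 lower (6 and 13 adjusted over the list alone, adjusted p = 0.15, 0.0384 with the replicate block), with Crtc3 at 0.71 ± 0.05 and S100a11 at -0.80 ± 0.08. That list had adjusted p = 0.494 with the block and an estimated correlation. Of 12 calcineurin and NFAT genes, 3 were higher and 1 lower (3 and 1 adjusted over the list alone, adjusted p = 0.251), led by the calcineurin regulator Rcan1 at 0.90 ± 0.08, Nfatc3 at 0.47 ± 0.04 and Nfat5 at 0.46 ± 0.07. Receptor calcium signalling genes of astrocytes had 4 of 29 higher and 6 lower (4 and 6 adjusted over the list alone, adjusted p = 0.79), with Rgs16 at 1.81 ± 0.13 and Rgs2 at 0.74 ± 0.05. Counts with the block were 3 higher and 4 lower of 18 for store-operated entry, 1 and 10 of 25 for pumps, exchangers and release channels, and 8 and 22 of 35 for calmodulin and calcium-binding genes. They were 6 and 4 of 12 for calcineurin and NFAT genes, and 5 and 11 of 29 for receptor calcium signalling.

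Oxidative stress genes under NRF2 control fell in 10 of 16 cases with thapsigargin (0 higher; 10 lower adjusted over the list alone), among them Gsta4 at -0.52 ± 0.07 and the peroxiredoxin gene Prdx1 at -0.41 ± 0.05 (camera adjusted p = 6.09e-04). That list had adjusted p = 0.761 with an estimated correlation. Cadherins, catenins and integrins fell in 9 of 24 cases (9 adjusted over the list alone), with Cdh13 at -0.24 ± 0.04 and Cdh11 at -0.18 ± 0.03 (adjusted p = 0.00327). That list had adjusted p = 0.662 with an estimated correlation. Medians were -0.181 for NRF2 targets, -0.195 for this list and -0.169 for XBP1 targets. Families of other function, chosen later, fell by like amounts. Their medians were -0.182 for cytosolic ribosomal proteins, -0.217 for complex I subunits and -0.133 for proteasome subunits, while zinc finger genes were at 0.504. The falls were therefore not particular to these lists. Lists that camera did not call were heat shock (7 higher and 2 lower of 17; 7 and 5 adjusted over the list alone; adjusted p = 0.681; Dnajb1 at 0.49 ± 0.05), p53 targets and apoptosis (5 and 2 of 19; 5 and 2 adjusted over the list alone; 0.601; Plk2 at 0.96 ± 0.04), SRF and YAP targets (7 and 6 of 21; 7 and 7 adjusted over the list alone; 0.92; Amotl2 at 1.66 ± 0.15), cholesterol synthesis (5 and 2 of 22; 5 and 2 adjusted over the list alone; 0.251; Insig1 at 0.79 ± 0.05) and hypoxia and glycolysis (3 and 3 of 17; 3 and 3 adjusted over the list alone; 0.92; Pfkfb3 at 0.70 ± 0.04). Fry called the first 2 of these (adjusted p = 0.00468 and 0.0103). In 9 lists of this contrast the median was below 0 and the mean above it: ATF4, ER chaperones, store-operated entry, receptor calcium signalling, heat shock, SRF and YAP targets, hypoxia, and the oligodendrocyte and progenitor markers. Mitochondrially encoded genes had 0 of 13 called in edgeR, and a median of -0.26 (adjusted p = 0.124, 0.042 with the replicate block). That list had adjusted p = 0.862 with the block and an estimated correlation, and adjusted p = 0.394 and a median of -0.14 with the block and the trend with exon length removed. Block counts were 0 higher and 18 lower of 24 for cadherins, catenins and integrins, 7 and 8 of 17 for heat shock, 6 and 6 of 19 for p53 targets and 10 and 5 of 22 for cholesterol synthesis. They were 4 and 6 of 17 for hypoxia and glycolysis, and 0 and 3 of 13 for mitochondrially encoded genes.

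Astrocyte markers were abundant, with Slc1a3, a glutamate transporter, at 2638 ± 83.0 CPM in control. With thapsigargin 1 of 16 was higher, Sox9 at 0.33 ± 0.07, and 4 were lower (1 and 4 adjusted over the list alone), among them Slc1a3 at -0.27 ± 0.05 and Fgfr3 at -0.33 ± 0.06. Microglia markers had 2 of 14 lower (0 adjusted over the list alone), P2ry12 at -0.45 ± 0.15 and Tyrobp at -0.36 ± 0.13, and a median of -0.40. Both lists gave adjusted p = 0.066, and 0.00177 and 3.22e-04 with the replicate block. The block with an estimated correlation gave adjusted p = 0.52 for astrocyte markers and adjusted p = 0.365 for microglia markers. P2ry12 was not called when control 1, 2 or 3, thapsigargin 2, 3 or 4, or calcium-free 2 or 3 was left out (adjusted p up to 0.117). Tyrobp was not called without any 1 of the libraries but control 4 and calcium-free 4 (up to 0.157). Oligodendrocyte lineage markers had 1 of 9 higher, Olig2 at 0.40 ± 0.05, and 1 lower, Cnp at -0.23 ± 0.06 (1 and 1 adjusted over the list alone, adjusted p = 0.985). Neuron markers had 1 of 12 higher, Gad1 at 0.29 ± 0.08, and 1 lower, Stmn2 at -0.34 ± 0.04 (1 and 1 adjusted over the list alone; 0.785). Ependymal and progenitor markers had 1 of 9 higher and 1 lower (1 and 2 adjusted over the list alone; 0.79), with Sox2 at -0.25 ± 0.04. Proliferation markers had 1 of 13 lower, Ccnb1 at -0.31 ± 0.08 (1 adjusted over the list alone; 0.786), and vascular and fibroblast markers 0 of 10 called (0 adjusted over the list alone; 0.889), with Kdr at 0.13 ± 0.11. Marker counts with the block were 1 higher and 11 lower of 16 for astrocytes, 0 and 12 of 14 for microglia, 1 and 4 of 9 for the oligodendrocyte lineage and 1 and 3 of 12 for neurons. They were 2 and 4 of 9 for progenitors, 1 and 4 of 13 for proliferation and 0 and 2 of 10 for vascular cells and fibroblasts. Besides Saraf, Atp2a2 and Stim2, given above, named genes lower only in the fit with the block were C1qa, Pcna, Cdk1, Rgs5, Nrarp, ATP6 and Prom1 (adjusted p of these from 1.04e-08 to 0.012).

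**Figure D2:**
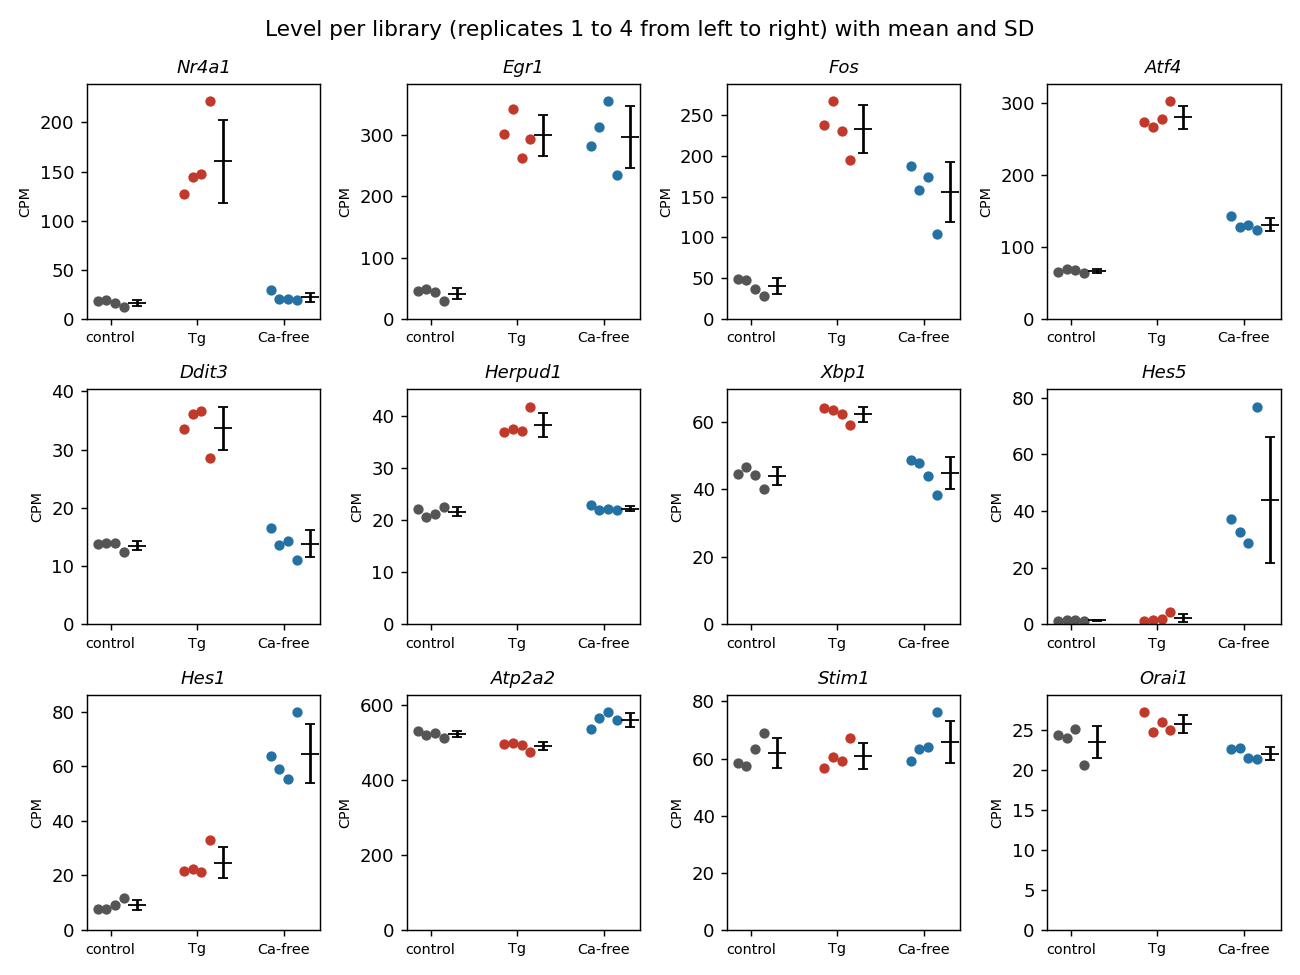
Levels in CPM of 12 genes, 1 point per library with replicates 1 to 4 from left to right, and the mean with SD of each group (n = 4). Nr4a1 has a mean of 16.4 CPM in control and 160.3 CPM with thapsigargin, Hes5 means of 1.39 CPM in control and 43.8 CPM in calcium-free medium, and Stim1 means of 62.0 and 65.8 CPM.

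Calcium-free medium raised Hes5 and Hes1, transcriptional repressors that Notch receptors induce. Hes5 (gene 15208, chromosome 4, 155042358 to 155046829) rose from 1.39 ± 0.171 to 43.8 ± 22.3 CPM (SD, n = 4), a log2 fold change of 4.98 ± 0.42. Hes1 (chromosome 16, 29883259 to 29886614) rose from 9.05 ± 1.77 to 64.6 ± 10.8 CPM, or 2.83 ± 0.18, and Nrarp, a Notch feedback gene, by 0.89 ± 0.15. Egr1 rose by 2.84 ± 0.16, Fos by 1.95 ± 0.21, Arc, an activity-regulated cytoskeletal gene, by 1.67 ± 0.11, and Gadd45g by 1.42 ± 0.09. The largest decreases were in the histone genes H2bc23 and H2bc24 at -1.43 ± 0.34 each, the nuclear noncoding RNA Neat1 at -1.30 ± 0.34, Vamp1 at -1.25 ± 0.27, Rhof at -1.16 ± 0.26 and the noncoding Mir100hg at -1.12 ± 0.22. Adjusted p for the 6 largest increases ran from 4.08e-06 to 3.94e-04, and for the decreases from 0.0114 to 0.0482. Neat1 was not called when any of 11 libraries was left out, all but replicate 1 of calcium-free medium (adjusted p up to 0.149), nor with the replicate block (0.073). Rhof was lost without any 1 control or calcium-free 2, 3 or 4 (up to 0.0913) and with the block (0.054). H2bc23 and H2bc24 were lost without control 1, 3 or 4, thapsigargin 3, or calcium-free 2 or 3 (up to 0.11), and Vamp1 without control 1 or calcium-free 2 (0.0619 and 0.0736). In calcium-free 1, Neat1 was at 239.6 CPM and Rhof at 21.16 CPM. Controls were at 269.5 to 323.5 and 25.52 to 33.34 CPM, and calcium-free 2, 3 and 4 at 57.85 to 95.78 and 6.887 to 11.84 CPM. The falls of Neat1 and Rhof therefore lay mainly in calcium-free 2, 3 and 4.

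In all, 646 genes were higher and 265 lower in calcium-free medium than in control with edgeR, and 15 and 63 changed at least 2-fold. With the replicate block 1771 were higher and 1197 lower. Higher genes made up 70.9% of calls with TMM factors and 58.5% with upper quartile factors. Single libraries moved these counts: 315 and 99 genes were called without control 1, 338 and 113 without control 2, 344 and 108 without control 3, 296 and 76 without calcium-free 2, 311 and 90 without calcium-free 3, and 849 and 600 without calcium-free 1. The lower count was also 170 without thapsigargin 2 and 162 without thapsigargin 3. Leaving out control 4 gave 665 and 195. The fit without the block leaves the difference of replicate 4 in its spread (biological coefficient of variation 12%, 4.3% with the block). Without replicate 2 of every group that fit called 50 and 9 genes, and the block 897 and 411. Single libraries were not left out with the block. Losses of calls without 1 library therefore cannot tell dependence on that library from this spread.

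Immediate early genes rose in 13 of 32 cases in calcium-free medium (0 lower; 14 adjusted over the list alone), with a median of 0.31 and camera adjusted p = 2.1e-13, and adjusted p = 0.106 with an estimated correlation. MAP kinase feedback regulators rose in 7 of 15 cases (8 adjusted over the list alone), with Dusp6 at 1.20 ± 0.06 and Spry2 at 0.91 ± 0.08. Their adjusted p was 1.17e-10, and 0.0349 with an estimated correlation, the lowest of the 28 lists in this contrast. The block with an estimated correlation ended that call (adjusted p = 0.383). The ATF4 and integrated stress response list had 5 of 28 higher (5 adjusted over the list alone), with Atf4 at 0.98 ± 0.06 and Ppp1r15a at 0.90 ± 0.07. Its adjusted p was 0.0181, with adjusted p = 0.106 with an estimated correlation, and its median of 0.02 was below 0 with upper quartile factors. Atf3 at 0.48 ± 0.12 was lost without any 1 library of replicates 1 to 3 (adjusted p up to 0.131), and Ddit3 was at 0.04 ± 0.11 (adjusted p = 0.958). SRF and YAP targets had 4 of 21 higher (6 adjusted over the list alone), with Amotl2 at 1.00 ± 0.15 and Ajuba at 0.43 ± 0.04 (adjusted p = 3.61e-04, and adjusted p = 0.499 with an estimated correlation). Inflammatory targets had 1 of 23 higher, Socs3 at 1.41 ± 0.14 (3 adjusted over the list alone; adjusted p = 0.00751, and adjusted p = 0.596 with an estimated correlation). The replicate block called 16 higher and 1 lower of the 32 immediate early genes, 8 and 1 of the 28 ATF4 genes, 7 and 0 of the 21 SRF and YAP targets, and 7 and 1 of the 23 inflammatory targets.

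Mitochondrially encoded genes were lower in calcium-free medium, with 1 of 13 called, ND1 at -0.62 ± 0.16 (11 lower adjusted over the list alone), a median of -0.49 and adjusted p = 6.9e-09. That list had adjusted p = 0.448 with an estimated correlation, and ND1 was lost without any 1 library but control 4, thapsigargin 4 and calcium-free 1 (adjusted p up to 0.141). With the replicate block 5 of the 13 were lower. Calcium-free 1 had 2.732% of its counts from mitochondrially encoded genes, within the 2.457% to 2.986% of the controls. Long noncoding RNAs had 4 higher and 59 lower of 1653 tested (12 and 180 with the block), with a median of -0.17. The mean number of detected genes differed from control by -685 (exact permutation p = 0.0286, the smallest possible; 0.129 adjusted over 9 tests; lower in all 4 pairs, exact sign-flip p = 0.125), and their share of mitochondrially encoded counts was 1.98 ± 0.525% against 2.73 ± 0.232% in control.

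Camera with TMM factors called no ER or calcium list in calcium-free medium, while fry called ER chaperones (adjusted p = 0.0482) and heat shock (0.00998). ER chaperones had 0 of 16 called (0 adjusted over the list alone; adjusted p = 0.0859, 0.0478 with RLE factors), XBP1 targets and ER-associated degradation 0 of 22 (0; 0.561), and unfolded protein response sensors 1 of 12 higher (2; 0.105). Store-operated calcium entry genes had 0 of 18 called (0; 0.273), with Orai2 at 0.28 ± 0.08 (adjusted p = 0.0546, 0.004 with the replicate block) and Stim1 at 0.09 ± 0.08. Calcium pumps, exchangers and release channels had 1 of 25 higher (3; 0.224), with Atp2a2 at 0.10 ± 0.03 (adjusted p = 0.113, 0.016 with the block). Calmodulin and calcium-binding genes had 2 of 35 higher (3; 0.383), calcineurin and NFAT genes 2 of 12 (2; 0.157), and receptor calcium signalling genes 2 of 29 (2; 0.395), with Rgs16 at 0.69 ± 0.13. Heat shock genes had 1 of 17 higher (2; 0.0859, 0.0494 with RLE factors), p53 targets 2 higher and 1 lower of 19 (3 and 1; 0.374), NRF2 targets 0 of 16 called (0; 0.561), cadherins, catenins and integrins 1 of 24 higher (1; 0.273), cholesterol synthesis 2 of 22 (2; 0.86), hypoxia and glycolysis 2 of 17 (2 and 1 lower; 0.524), and clock genes 2 higher and 3 lower of 17 (2 and 3; 0.271), with Cry2 at -0.30 ± 0.04. The counts in parentheses are adjusted over the list alone. Cdh11 at 0.13 ± 0.03 was lost without any 1 library but thapsigargin 3, thapsigargin 4 and calcium-free 1 (adjusted p up to 0.124), Mdm2 at 0.27 ± 0.06 without control 1, 2 or 3 or calcium-free 2 or 3 (up to 0.0863), and Chordc1 at 0.21 ± 0.05 without control 2 or 3 or calcium-free 2 (up to 0.0869). Block counts were 3 of 16 higher for ER chaperones, 4 of 12 for sensors, 1 of 18 for store-operated entry, 6 of 25 for pumps, exchangers and release channels, and 5 of 17 for heat shock. They were 6 higher and 3 lower of 29 for receptor calcium signalling, 4 and 4 of 19 for p53 targets, 3 and 1 of 24 for cadherins, catenins and integrins, 1 and 5 of 22 for cholesterol synthesis, and 3 and 1 of 17 for hypoxia and glycolysis.

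Cell type markers showed 2 calls in calcium-free medium in the fit without the block, Olig2 at 0.48 ± 0.05 of the oligodendrocyte lineage list (1 of 9 higher; 2 adjusted over the list alone; camera adjusted p = 0.273) and Hes5 of the progenitor list (1 of 9; 1 higher and 1 lower adjusted over the list alone; 0.224). The lists of astrocytes (0 of 16; 0.86), microglia (0 of 14; 0.114, and 2.21e-04 with the replicate block), neurons (0 of 12; 0.803), vascular cells and fibroblasts (0 of 10; 0.342) and proliferation (0 of 13; 0.758) held no called gene in that fit, over all genes or adjusted over the list alone. Microglia markers had adjusted p = 0.383 with the block and an estimated correlation. The block called 6 of 14 microglia markers lower, and 1 of 16 astrocyte, 1 of 12 neuron, 2 of 10 vascular and fibroblast, 1 of 13 proliferation and 2 of 9 oligodendrocyte lineage markers higher. Of the 9 progenitor markers it called 3 higher and 1 lower. Besides Orai2 and Atp2a2, given above, named genes higher in calcium-free medium only in the fit with the block were Tnfaip3, Atf6, Kdr, Dnajb1, Micu3, Sox9, Plk2, Hspa5, Cxcl1 and Cspg4 (adjusted p of these from 0.00262 to 0.0177). Those lower were Ccnf, C1qa, B4galt5, ATP6, Sox2, Tram1l1, Rgs2, Ccne2, ATP8, Tyrobp and Cemip2 (2.12e-07 to 0.0343).

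Thapsigargin and calcium-free medium were also compared directly. No group received the drug in calcium-free medium, so this contrast cannot separate store depletion from loss of external calcium. Nr4a1 was higher with thapsigargin by 2.87 ± 0.20, Rgs1 by 1.82 ± 0.15, Nr4a2, a nuclear receptor of the same family, by 1.68 ± 0.14, Map3k14 by 1.64 ± 0.07, and H2bc23 and H2bc24 by 1.75 ± 0.34 each. Hes5 was lower by 4.29 on the log2 scale (-4.29 ± 0.40), Hes1 at -1.40 ± 0.17, Cemip2 at -1.18 ± 0.15, Nrarp at -1.14 ± 0.15, B4galt5 at -1.01 ± 0.11 and Megf6 at -0.94 ± 0.07. Egr1 was at 0.02 ± 0.15 between the treatments (adjusted p = 0.955). In all 2498 genes were higher and 2259 lower with edgeR (214 and 12 at least 2-fold), and 3833 and 4595 with the replicate block.

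Of the named stress genes, Atf4 was higher with thapsigargin than in calcium-free medium by 1.10 ± 0.05, Atf3 by 1.56 ± 0.12, Ddit3 by 1.28 ± 0.11 and Herpud1 by 0.79 ± 0.05. The ATF4 list had 7 higher and 5 lower of 28 (7 and 7 adjusted over the list alone; camera adjusted p = 0.846). Immediate early genes had 25 of 32 higher (25 higher and 1 lower adjusted over the list alone; adjusted p = 2.73e-13), with adjusted p = 0.186 with an estimated correlation. MAP kinase feedback genes had 6 of 15 higher (7; 0.0218), with adjusted p = 0.516 with an estimated correlation. Inflammatory targets had 10 higher and 2 lower of 23 (10 and 2; 0.0218), with adjusted p = 0.703 with an estimated correlation. Clock genes had 8 higher and 1 lower of 17 (9 and 1; 2.97e-04), with adjusted p = 0.186 with an estimated correlation. The XBP1 list had 2 higher and 11 lower of 22 (2 and 12; 0.0025), with adjusted p = 0.279 with an estimated correlation. NRF2 targets had 8 of 16 lower (10; 4.33e-04), with adjusted p = 0.586 with an estimated correlation. Cadherins, catenins and integrins had 11 of 24 lower (11; 2.31e-04), with adjusted p = 0.47 with an estimated correlation. With the block the counts were 8 higher and 12 lower of 28 for ATF4, 27 and 1 of 32 for immediate early genes, 9 and 2 of 15 for MAP kinase feedback and 12 and 4 of 23 for inflammatory targets. They were 13 and 1 of 17 for clock genes, 0 and 13 of 16 for NRF2 targets and 0 and 18 of 24 for cadherins, catenins and integrins. The counts in parentheses are adjusted over the list alone.

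Camera called 2 of 5 calcium lists between the treatments, both lost with an estimated correlation. Pumps, exchangers and release channels had 1 higher and 7 lower of 25 with thapsigargin (1 and 9 adjusted over the list alone; adjusted p = 0.0231), with Atp2a2 at -0.19 ± 0.03 (adjusted p = 0.00127). That list had adjusted p = 0.703 with an estimated correlation. Calmodulin and calcium-binding genes had 3 higher and 11 lower of 35 (3 and 14; 0.0301), with adjusted p = 0.651 with an estimated correlation. Store-operated entry genes had 3 higher and 1 lower of 18 (3 and 1; 0.724), with Orai1 at 0.22 ± 0.06, which was lost without thapsigargin 1 or calcium-free 3 (adjusted p = 0.0541 and 0.053). Astrocyte markers had 4 of 16 lower (4; 0.0337), with adjusted p = 0.529 with an estimated correlation. Mitochondrially encoded genes had a median of 0.23 and 0 of 13 called in edgeR (0; 0.049), with adjusted p = 0.795 with an estimated correlation, and the list was lost with RLE (0.0612) and upper quartile factors (0.0711). Calcineurin and NFAT genes had 2 higher and 2 lower of 12 (3 and 2; 0.529; 5 and 4 with the block) and receptor calcium signalling genes 3 higher and 6 lower of 29 (3 and 6; 0.369; 4 and 12 with the block). Camera called none of the other lists, with adjusted p of 0.0603 for SRF and YAP targets (0.025 with the replicate block), 0.139 for cholesterol synthesis (0.0205 with the block), 0.306 for microglia markers (0.0125 with the block), 0.0889 for ER chaperones and 0.115 for unfolded protein response sensors. The block with an estimated correlation gave adjusted p = 0.521 for SRF and YAP targets, 0.521 for cholesterol synthesis and 0.504 for microglia markers. Fry called ER chaperones (adjusted p = 0.00731), the sensors (0.0106), ATF4 (0.0255), p53 targets (0.0415) and SRF and YAP targets (0.0479). Fos at 0.58 ± 0.20 was lost without any 1 library but control 1, control 4, thapsigargin 4 and calcium-free 1 (up to 0.118), Vamp1 without any but control 4 and calcium-free 1 (up to 0.107), and Sox2 without any but control 4 and thapsigargin 4 (up to 0.165). Leaving out 1 library also ended the call of Npas4 at 0.66 ± 0.18 without thapsigargin 3 (0.0513), and of Neat1 and Mir100hg without calcium-free 2 (0.0565 and 0.057). The block called 1 higher and 13 lower of the 25 pumps, exchangers and release channels, 5 and 21 of the 35 calmodulin and calcium-binding genes, 3 and 6 of the 18 store-operated entry genes, 1 and 11 of the 16 astrocyte markers, and 4 and 0 of the 13 mitochondrially encoded genes. Named genes that only the block called were Sox9, Hk2, ND1 and ATP6, higher with thapsigargin (adjusted p from 0.00202 to 0.0316). Those lower were Ccnf, Pcna, C1qa, Stim2, Rgs5, Cdk1, Saraf, Cnp, P2ry12, Dlx1, Stim1 and Kdr (3.88e-07 to 0.038).

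**Figure D3:**
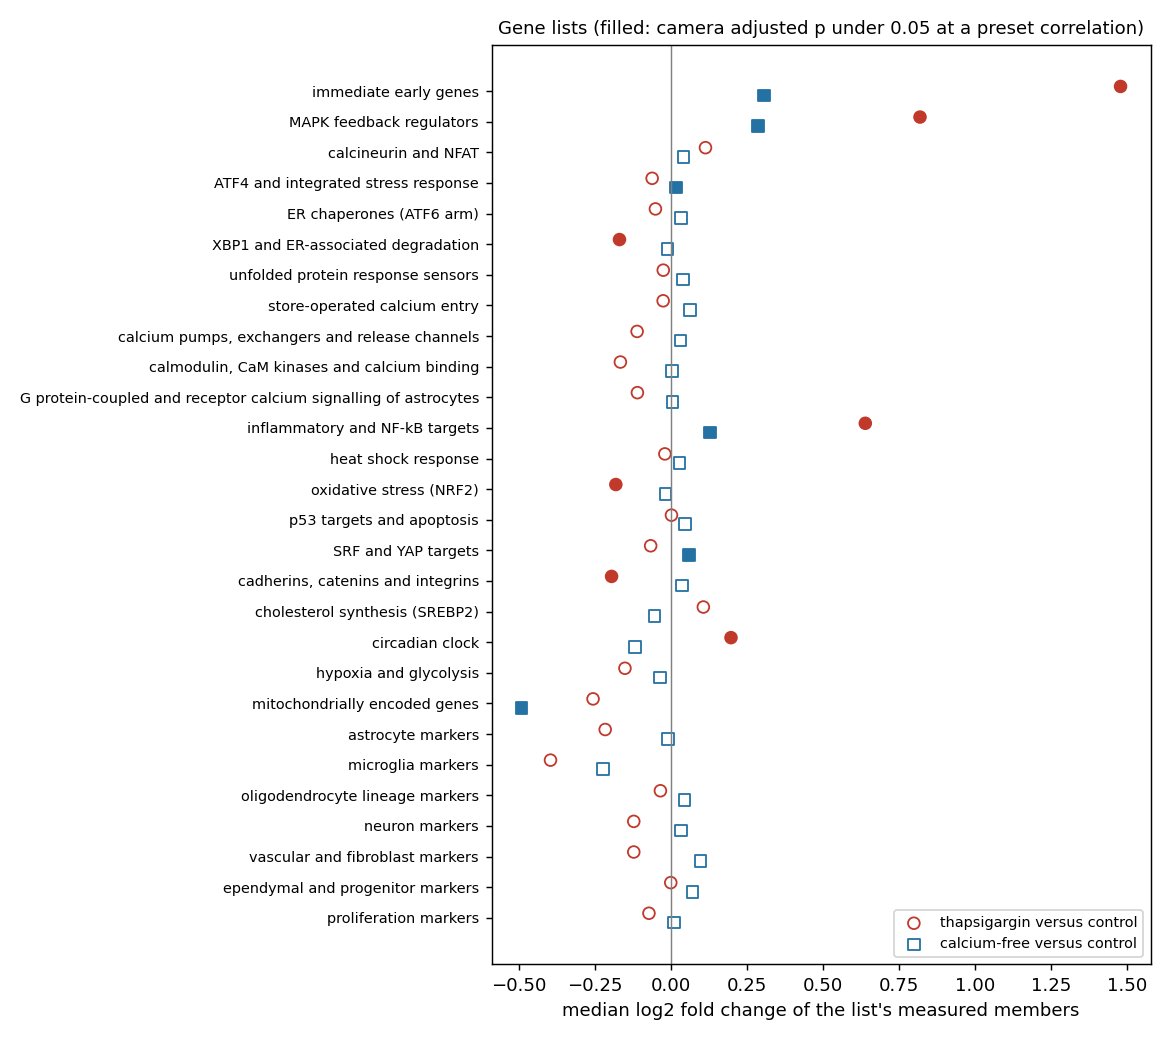
Median log2 fold change of the measured members of each gene list against control, with circles for thapsigargin and squares for calcium-free medium, filled where camera gave an adjusted p under 0.05 at the preset correlation. Immediate early genes have a median of 1.48 with thapsigargin and 0.31 in calcium-free medium, and the mitochondrially encoded genes -0.26 and -0.49.

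Fold changes of the treatments against the same controls went together across the 17077 genes (Pearson r = 0.394, Spearman rho = 0.407; genes are not independent replicates). Simulated unchanged groups, set against controls that were simulated as well, gave a mean r of 0.507, from 0.491 to 0.524 in 20 simulations. Shared controls alone give such a value, and treatment effects can lower it. Setting r beside it therefore cannot show whether the responses were shared. The covariance was 0.0322 against 0.00972 in the simulations, a difference of 0.0224, or 0.0108 against simulations without shared replicate terms. With the controls split between the treatments, r was 0.043 to 0.205, and 0.15 to 0.245 with the replicate block. Among called genes 548 were higher under both treatments, where independent lists, which leave out that the contrasts share controls, give 105.9, and they made up 84.8% of those higher in calcium-free medium. Of lower genes 57 were shared, where independent lists give 39.28. They made up 21.5% of those lower in calcium-free medium, and another 26 of these were higher with thapsigargin. With the replicate block 1288 higher and 493 lower genes were shared, where independent lists give 406.5 and 337.6. Among the shared increases were Egr1, Fos, Atf4, Dusp6 and Hes1.

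**Figure D4:**
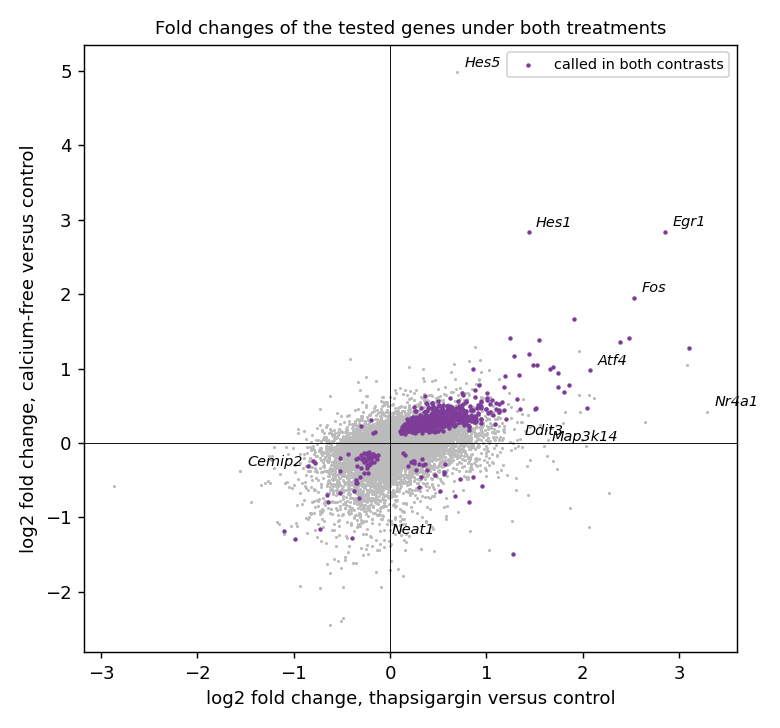
Log2 fold changes of each tested gene with thapsigargin and in calcium-free medium, both against control, with genes called in both contrasts in purple. Egr1 lies at 2.86 and 2.84, Nr4a1 at 3.29 and 0.42, and Hes5 at 0.70 and 4.98.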

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

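Tests chosen only after the result was seen were those of single libraries, of progenitor cells, of RNA recovery and of depth. The length correction and the lists of Notch and IRE1 targets were chosen after the patterns they address were seen, the Notch list leaving out the genes seen to rise, but before the results of those tests. The test of other splits of the libraries was set beforehand.

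A library far from the others of its group was found in 38 of 351 groups of 4 tested, where chance gives about 1 in 20, and 33 of the 38 were replicate 4. In controls, replicate 4 stood apart with Atf3 at 6.32 CPM, C1qa at 16.7, Ccnb1 at 140, Ccnf at 44.9, Cdk1 at 253, Ddit3 at 12.4, Mcl1 at 149, Nfil3 at 13.1, Pcna at 240, Rgs16 at 44.3, Saraf at 166, Stim2 at 31.7 and Txn1 at 230 CPM. Control 3 stood apart with Dnajc10 at 221 CPM. With thapsigargin, replicate 4 had ATP6 at 2120 CPM, Ccnb1 at 112, Ccnf at 23.8, Cdk1 at 219, Fgfr3 at 92.9, Gad1 at 21.1, Herpud1 at 41.8, Hes1 at 33, Hes5 at 4.27, Mbtps1 at 168, Nrarp at 19.6, Olig2 at 357, S100a11 at 110, Saraf at 156 and Stmn2 at 110 CPM, and thapsigargin 1 had Rhof at 13.9 CPM. In calcium-free medium, replicate 4 had Adm at 8.43 CPM, B4galt5 at 52.4, Ccnf at 30.3, Cnp at 186 and Nfil3 at 13.9 CPM, and calcium-free 1 had Arc at 15.3, Dnajc10 at 215 and Nr4a1 at 29.1 CPM.

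The response of replicate 4 differed from that of replicates 1 to 3 by an interaction test in edgeR for Zfp131, by 0.575 in log2 fold change for thapsigargin versus control (adjusted p = 0.0326) and by 0.556 for thapsigargin versus calcium-free medium (0.0397), and for Spry2 by 0.448 in the latter (0.0404). Zfp131 was chosen after its values were seen. No gene differed for calcium-free medium versus control, where 1107 genes had an unadjusted p under 0.05. Replicate 4 is 1 library per group, so each interaction rests on single libraries. It also differs from the others in sex, so effects of sex and of any other difference of its culture were not separated.

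Hes5, Hes1 and Nrarp were higher in calcium-free medium than in control. A single library is argued against, since all 3 genes were called with any 1 library left out (adjusted p up to 0.0246), although Nrarp was not without replicate 2 of every group (0.104), and more progenitor cells are argued against, since the other 8 progenitor markers had a median log2 fold change of 0.0522 (SD 0.0914) beside 4.98 for Hes5. A Notch response may be the source, but it stays open: the 7 other Notch targets gave camera p = 0.0658 (0.016 with the replicate block, 0.274 with an estimated correlation), and 1 of the 7 was called higher (2 with the block). With thapsigargin 3 of the 7 were called higher and 1 lower (camera p = 0.0435, and p = 0.233 with an estimated correlation), and Hes1 was at 1.44 ± 0.18 (adjusted p = 7.11e-05), Hes5 at 0.70 ± 0.45 (0.285) and Nrarp at -0.25 ± 0.15 (0.237). Calcium holds Notch receptors together at the cell surface, as background, and receptor cleavage was not measured.

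The XBP1 and ER-associated degradation, NRF2 and cadherin lists were lower with thapsigargin. A trend with gene length is argued against as the whole cause. With the trend removed and the replicate block in the fit, the median of NRF2 targets went from -0.179 to -0.162. Camera still called that list at the preset correlation. The medians of the XBP1 and cadherin lists went further down, from -0.168 to -0.189 and from -0.19 to -0.26. The trend therefore did not lower these lists, so camera's calls of them in that fit were no further test. With an estimated correlation that fit gave adjusted p = 0.582 for the XBP1 list, 0.501 for NRF2 targets and 0.516 for the cadherin list, so the lists themselves were not called. Whether decay of RNAs by IRE1, an ER stress sensor that cuts RNAs at the ER, contributes stays open: 6 known targets were lower as a list (camera p = 0.0178), but p was 0.299 with an estimated correlation. Genes of proteins outside the ER were called lower as well. These were 34 of 37 nuclear-encoded complex I subunits, 41 of 76 cytosolic ribosomal proteins and 22 of 37 proteasome subunits, with 1 proteasome subunit higher. With an estimated correlation camera gave these families adjusted p = 0.117, 0.336 and 0.27. The test does not single out IRE1 targets, since collagens were called lower in 8 of 39 cases (21 with the replicate block, adjusted p = 0.0224, and adjusted p = 0.507 with an estimated correlation) and glycosyltransferases in 15 of 46 (adjusted p = 2.66e-04, and adjusted p = 0.117 with an estimated correlation), beside 2531 of all 17077 genes, and lower transcription was not tested.

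Nuclear noncoding and mitochondrially encoded RNAs were lower as lists in calcium-free medium. Calcium-free 1 shared little of this. Its median log2 deviation from the mean of all libraries was 0.221 for nuclear noncoding and 0.264 for mitochondrially encoded RNAs. Controls were at 0.273 to 0.391 and 0.117 to 0.413, and calcium-free 2, 3 and 4 at -0.954 to -0.652 and -0.582 to -0.249. Of 11 nuclear noncoding RNAs, a list chosen after values were seen, 2 were called lower (camera p = 3.94e-06, and p = 0.0672 with an estimated correlation), of which Neat1 was lost with the replicate block (adjusted p = 0.073), and 1 of 13 mitochondrially encoded genes was called (adjusted p = 6.9e-09, and adjusted p = 0.448 with an estimated correlation). A single library is argued against for the mitochondrially encoded list, whose median log2 fold change stayed at or below -0.435 with any 1 library left out, and depth is argued against for the fewer genes detected, since after thinning each calcium-free library detected at least 183 fewer genes than each control. RNA recovery that differed between libraries may contribute: within groups the levels of both kinds of RNA went together over the 12 libraries (Pearson r = 0.822, exact permutation p = 0.0496, Spearman rho = 0.734, exact p = 0.0323), r was 0.585 without the 2 libraries farthest out, and 0.979 without replicate 4 (exact p = 0.00463). Recovery itself was not measured. An effect of the medium that varied in strength between libraries would give the same correlation, so this test cannot tell them apart. Recovery and an effect of the medium on these RNAs can both hold, and no biological explanation was tested.

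Of the 35 splits of the 8 libraries of a contrast, 1 gave as many calls, the real split. The real count was 5331 for thapsigargin versus control, with 0 as the highest of the other splits, 911 with 115 for calcium-free medium versus control, and 4757 with 0 for thapsigargin versus calcium-free medium, all in edgeR. These splits leave the replicate numbers out of account. Only 8 splits part all 4 pairs of replicate numbers as the real one does, too few for a share under 0.05, and the highest other count among them was 0 in each contrast.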

How the results depend on the processing

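Tests chosen after the results were seen were the replicate block with 1 replicate number left out, the block for replicate 4 alone, the fit without mitochondrially encoded genes, the length correction, the split controls with the block, the shared correlation without each replicate number, upper quartile factors for lists, and the length correction with the block for lists. Across 28 lists in 3 contrasts, 760 list values kept their side of the threshold under the alternatives, 46 passed it newly and 34 fell short of it, 23 of these 34 with an estimated correlation. The 760 include lists not called in the main fit whose direction changed, such as oligodendrocyte lineage markers with thapsigargin under the replicate block. For named genes 9162 values stayed on their side, 447 passed newly and 300 fell short. No list or named gene called in the main fit reversed its direction. Of 212 named gene differences called, 160 were called in every alternative that gave a value. No called named gene changed direction with RLE or upper quartile factors, which moved the median log2 fold change of all genes to -0.03 and -0.08 with thapsigargin (-0.05 with TMM). Calls of lists were lost without 1 replicate number in calcium-free medium for ATF4 (0.058 and 0.0786 without replicates 1 and 4) and inflammatory targets (0.0576 without replicate 1, 0.221 with fry), and between treatments for calcium pumps (0.0519) and astrocyte markers (0.0536) without replicate 3, and mitochondrially encoded genes (0.105 and 0.298 without replicates 2 and 3, 0.212 with fry). Where not stated, the cause was not tested.

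DESeq2 called 1058 genes higher and 428 lower in calcium-free medium. Without a filter on low counts, which tests more genes, 1456 genes were lower with thapsigargin, 175 in calcium-free medium and 1247 between treatments. With only the 8 libraries of the contrast, and so fewer samples, 404 and 96 genes were called in calcium-free medium. Calls of at least 2-fold were 170 and 20 with thapsigargin, 15 and 63 in calcium-free medium, and 214 and 12 between treatments. With 1 library left out, counts ran from 2361 to 3031 higher and 1924 to 2719 lower with thapsigargin, 296 to 849 and 76 to 600 in calcium-free medium, and 1993 to 2654 and 1623 to 2545 between treatments. Without 1 replicate number, which leaves 9 libraries, they ran from 1886 to 4147 and 1085 to 3598 with thapsigargin, 50 to 1782 and 9 to 877 in calcium-free medium, and 1363 to 3684 and 784 to 3293 between treatments, lowest without replicate 2 and highest without replicate 4.

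With the replicate block 4817 genes were lower with thapsigargin, 1771 higher and 1197 lower in calcium-free medium, and 3833 and 4595 between treatments. It kept 2797 and 2526 of the calls with thapsigargin, 641 and 257 in calcium-free medium, and 2490 and 2250 between treatments, and called 11 lists with thapsigargin in place of 7. Beyond the block values given with the results, it changed no other list call at the preset correlation, and with an estimated correlation it ended the call of MAP kinase feedback regulators in calcium-free medium (adjusted p = 0.383). Among the 114 named genes it added 12 calls with thapsigargin, 23 in calcium-free medium and 16 between treatments, and ended 2, those of Neat1 and Rhof in calcium-free medium. With the block and replicate 1 left out, 4701 genes were lower with thapsigargin, 2196 and 1902 were called in calcium-free medium, and 4167 and 4783 between treatments. Without replicate 2 it gave 411 lower in calcium-free medium, without replicate 3 it gave 4095 lower with thapsigargin, 1068 and 553 in calcium-free medium and 3791 lower between treatments, and without replicate 4 it gave 1565 and 663 in calcium-free medium. A block for replicate 4 alone gave 4955 lower with thapsigargin, 1886 and 1383 in calcium-free medium, and 3920 and 4728 between treatments. The block with the length correction gave 4798 lower with thapsigargin, 2207 and 970 in calcium-free medium, and 5649 lower between treatments. For lists it ended no call of the main fit. It ended the block's call of mitochondrially encoded genes with thapsigargin, and in calcium-free medium it newly called ER chaperones (0.00154), heat shock (0.00467) and clock genes (0.0401).

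With an estimated correlation 0 lists were called with thapsigargin, 1 in calcium-free medium and 0 between treatments, against 7, 6 and 11 at the preset one, and 4, 4 and 3 lists had an unadjusted p under 0.05. Fry, which asks whether a list moves one way, called 12 lists with thapsigargin and 17 between treatments. Beyond those named with the results it called, with thapsigargin, ATF4 (1.58e-05), calcineurin and NFAT (0.00676) and astrocyte markers (0.00946), and oligodendrocyte lineage markers in calcium-free medium (0.0345) and between treatments (0.0302), where it also called progenitor markers (0.0106). The correlation of the treatments' fold changes was 0.0582, 0.064, 0.202, 0.043, 0.194 and 0.205 over the 6 splits of the controls, which share no control library, and 0.15, 0.183, 0.195, 0.199, 0.212 and 0.245 with the block. It was 0.515 among genes with an average log2 CPM of at least 4, and 0.331 to 0.424 without 1 replicate number. On simulated data for thapsigargin versus control, 22% of genes at the smallest simulated change and 68% at 1.5-fold were recovered, so the fit without the block often missed simulated changes under 1.5-fold. The block recovered 74% and 86%, and DESeq2 42% and 78%. The lead of the block was built in, since the counts were drawn from its own fit.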

Other observations

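The gene families below were chosen after their values were seen, and all tests in this part are of that kind. With thapsigargin, genes of zinc finger proteins, most of them transcriptional regulators, were higher in 240 of 346 cases and lower in 4, with a median log2 fold change of 0.50 (camera adjusted p = 2.02e-32 over 12 families, adjusted p = 0.117 with an estimated correlation, 0.0458 with the replicate block and an estimated correlation). Kruppel-like factors, a group of growth-regulating transcription factors, were higher in 10 of 14 cases (adjusted p = 3.72e-08, adjusted p = 0.0678 with an estimated correlation). Klf2, Klf4, Klf6 and Klf10 are also on the immediate early gene list, so this family is not independent of that list. Called lower were 34 of 37 nuclear-encoded complex I subunits (adjusted p = 3.64e-15, adjusted p = 0.117 with an estimated correlation), 41 of 76 cytosolic ribosomal proteins (1.32e-11, adjusted p = 0.336 with an estimated correlation), 22 of 37 proteasome subunits (1.59e-07, adjusted p = 0.27 with an estimated correlation) and 9 of 17 vacuolar ATPase subunits (2.66e-04, adjusted p = 0.142 with an estimated correlation). Smaller parts of other families were called lower, 10 of 25 nucleotide sugar transporters (0.0066, adjusted p = 0.0678 with an estimated correlation), 15 of 46 glycosyltransferases (2.66e-04, adjusted p = 0.117 with an estimated correlation) and 8 of 39 collagens (0.0224, adjusted p = 0.507 with an estimated correlation), beside 2531 of all 17077 genes. Regulators of G protein signalling were higher in 5 of 18 cases (0.0442, adjusted p = 0.27 with an estimated correlation), with a median of 0.02 that was below 0 with upper quartile factors, and small nucleolar RNA host genes had 6 higher and 2 lower of 16 (0.0737). With the replicate block 76 of 76 ribosomal proteins, 14 of 17 vacuolar ATPase subunits and 21 of 39 collagens were lower, as were 10 zinc finger genes and 4 small nucleolar RNA host genes. Kruppel-like factors had adjusted p = 0.0458 with the block and an estimated correlation. Fold changes in this contrast went with exon length (Spearman rho = 0.272). With that trend removed and the block in the fit, camera gave adjusted p = 3.5e-31 for zinc finger proteins, 7.92e-08 for Kruppel-like factors, 6.22e-05 for complex I, glycosyltransferases and collagens, 6.58e-05 for ribosomal proteins, 0.00633 for the proteasome, 0.00493 for vacuolar ATPase subunits and 0.0034 for nucleotide sugar transporters. Regulators of G protein signalling were lost (0.0732) and small nucleolar RNA host genes were called (0.00633).

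In calcium-free medium replication-dependent histone genes were lower in 11 of 54 cases (29 with the replicate block), with a median of -0.55 (camera adjusted p = 1.75e-18, adjusted p = 0.424 with an estimated correlation). With thapsigargin 1 of the 54 was lower (6 higher and 3 lower with the block), and between the treatments 26 were higher with thapsigargin (adjusted p = 4.35e-10, adjusted p = 0.194 with an estimated correlation). Most histone mRNAs of this class lack a poly-A tail, so their level in poly-A libraries also depends on how the RNA was captured. As a group the calcium-free libraries also had fewer counts from mitochondrially encoded genes, 1.98 ± 0.525% against 2.73 ± 0.232% in control (SD, n = 4). Calcium-free 1, at 2.732%, lay within the range of the controls.

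Fold changes went with exon length over 14680 coding genes, with a Spearman rho of 0.272 for thapsigargin versus control, 0.271 for calcium-free medium versus control and 0.136 between the treatments. With each library's length trend removed rho was 0.0342, 0.0371 and 0.0205. Genes are not independent replicates, so no p is given.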
